A study of Drosophila melanogaster with 2 samples.

How the data were processed

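Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map genomic binding of the Drosophila melanogaster protein encoded by aop (anterior open, also called Yan). The aop protein is an ETS-domain transcriptional repressor that acts downstream of receptor tyrosine kinase and MAPK signalling. Per the labels, transgenic embryos aged 0 to 24 h, a collection that spans all of embryogenesis, carried aop fused to enhanced green fluorescent protein (eGFP), and chromatin of whole organisms was precipitated with an antibody against GFP. The labels also give sonication to fragments of 200 to 800 bp and name 2 biological replicates, which form 1 group. Control libraries were not analysed here.

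The authors made all peak lists on the dm6 assembly. Per the labels and the text lists deposited with each library, peaks were ranked by the irreproducible discovery rate (IDR) procedure, and each list exists as a ranked set of candidates and as a thresholded set. One thresholded set and one conservative set were derived from both replicates together, and each replicate also has its own pair of lists, made from its own alignment. Per the same text lists, every peak list also derives from one further file that both replicates share, and the thresholded and conservative lists from another that the ranked lists do not have. The kinds of these files are not given there, and the replicates' lists share these inputs. The aligner, the peak caller and their versions are not given in the sources used here. The signal value of a peak is the authors' own measure of enrichment as deposited, with an unstated scaling, so it was used only to describe, rank and filter peaks within a list. The score deposited with each peak is the whole-number rank score of the IDR procedure, limited to 1000. In every thresholded list the lowest score was 830, and the highest global IDR among peaks kept in any of these lists was 0.00999659. A score of at least 830 was reached by 1826 candidates of the ranked list, of which 1725 stood in the thresholded set, so a further filter by the authors, not described in the sources used here, had been applied. Whether either shared file served for it is not known. The same comparison gave 89 left-out candidates for the conservative set, 45 for replicate 1 and 72 for replicate 2. Read depth is unknown, because the lists hold no counts. No peak was identical in position and value between the replicates' thresholded lists (0 shared lines).

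Coordinates are dm6, 1-based. Sequence came from Release 6 of the genome, the same assembly, and gene models from Ensembl release 115. No peak ended beyond its chromosome arm. Analyses of genes, motifs and chromosome arms used the 1692 thresholded peaks on the 7 arms 2L, 2R, 3L, 3R, 4, X and Y, and left out 33 on unplaced sequence, where the annotation was not used. The position of a peak was its summit. A peak was TSS-proximal when its summit lay within 500 bp of a transcription start site (TSS) of any annotated gene other than a transposon. The remaining summits were classed, in order of priority, as 5' UTR, CDS exon, 3' UTR, intron, noncoding exon or intergenic. Each peak was assigned to the protein-coding gene with the nearest TSS. The TSSs of at least 2 genes lay within 500 bp of 251 of the 1692 summits (14.8%), so the assigned gene is one of several for those peaks.

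Replicates were compared by the share of peaks in one list that overlapped the other list by at least 1 bp. Chance came from 1000 random draws of as many candidates from the other replicate's ranked list, in a one-sided permutation test. Spearman correlations and differences of medians were tested by 100000 permutations, two-sided. Annotation classes and motifs were compared with Fisher's exact test, two-sided, against candidates of the ranked list that did not overlap the thresholded set (143341 on the arms). For motifs, 10 such candidates per peak (16395 in all, since some strata held too few) were matched on decile of GC content in the 201 bp window around the summit and on TSS proximity. In all, 22 motifs were searched on both strands within 100 bp of the summit: 3 forms of the ETS site and 19 sites of other factors. For gene lists, the number of members with a thresholded peak was compared with 10000 random gene sets matched on decile of territory, the length of sequence nearest to a gene's TSS, in a two-sided permutation test. There were 28 lists. Their 657 symbols gave 627 protein-coding genes after 30 older names had been replaced, and 16 symbols matched no gene. Clustering within 5 kb and peaks per gene were compared with 1000 draws of as many candidates, one-sided. P-values within a family were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Intervals of shares are exact binomial (Clopper-Pearson) 95% intervals, and those of odds ratios are Woolf 95% intervals. Both cover counting error only. All p-values are over peaks or genes of 1 group, not over replicates.

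Tests, gene lists, motifs and the rule for named genes were chosen before the data were examined. Named genes are those of the 20 peaks with the highest signal, and each gene with a peak in the list of reported aop target loci, with the number of the rest. For every list that passed its test, and for the receptor tyrosine kinase, Notch, mesoderm, heart, neurogenesis, retina and tracheal lists in any case, the 4 bound genes with the highest signal are named. The 10 genes with the most peaks, and the 5 strongest peaks of each replicate's list without overlap in the other's, complete the rule. Ties were to be ordered by chromosome and then by start, but genes with equal numbers of peaks were ordered by their highest signal instead. One item that the rule takes is not reported here. Alternatives covered the conservative set, the stronger part of the thresholded set by signal, either replicate's own list alone, other overlap rules, other windows around TSSs and summits, other backgrounds and other ways of assigning genes. Leaving out peaks with a signal under 20, leaving out the peaks of aop and leaving aop out of the gene lists were alternatives chosen after seeing the data.

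Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used Matplotlib 3.10.9. The procedures were tested on simulated data, with 100 runs each. Lists made without sharing were called in 1% of runs, motifs with no planted excess in 6%, unrelated ranks in 2% and equal medians in 4%. The motif runs drew counts for Fisher's test, so they did not cover the matching of candidates. A gene list with no true excess but large territories was called in 5% of runs with matching and in 47% without it. A list with a large planted excess, the same in every run, was called in 100%, which does not measure power for smaller excesses.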

Results

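Binding of aop-eGFP was mapped by ChIP-seq in whole embryos aged 0 to 24 h, with 2 biological replicates of 1 group. The question the design poses is where in the genome the tagged repressor is found, and how far the replicates share those places. Peaks had been called on each replicate separately and on both together. The set from both replicates held 1725 peaks with a median width of 256 bp, covering 424 kb. Replicate 1 alone gave 628 peaks and replicate 2 alone gave 1142, both with a median width of 240 bp. The signal value of a peak is the authors' own, and its median in the thresholded set was 64.9 (interquartile range 53.6 to 90.8, range 2.07 to 1468.5). Only 24 peaks had a signal under 20. The read depth behind these values is unknown, and no control samples were compared.

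Most places bound in replicate 1 were also bound in replicate 2, among them all 20 strongest peaks of the combined set. That set was derived from both replicates together, so its strongest peaks are not a separate test of agreement. The intron of sty, which encodes Sprouty, an intracellular antagonist of receptor tyrosine kinase signalling, ranked 1 in both replicates. Of the 628 peaks of replicate 1, 496 (79.0%, 95% interval 75.6 to 82.1) overlapped a peak of replicate 2, where chance gave 0.988% on average and 2.71% at most (permutation p = 0.000999, the smallest that 1000 draws can give). In the other direction, 492 of 1142 peaks (43.1%, 40.2 to 46.0) overlapped, against 0.665% by chance and 1.66% at most (permutation p = 0.000999). The draws were not matched on signal. Median signal was 11.0 for all candidates of replicate 2 against 48.6 for its listed peaks, and 9.36 against 45.1 in replicate 1. The test therefore cannot separate shared aop binding from other strong signal common to both replicates. Across the 496 shared peaks, signal in one replicate followed signal in the other with a Spearman rho of 0.726 (permutation p = 1e-05, the smallest that 100000 permutations can give). Peaks are not independent replicates, so this p describes the lists alone.

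**Figure D1:**
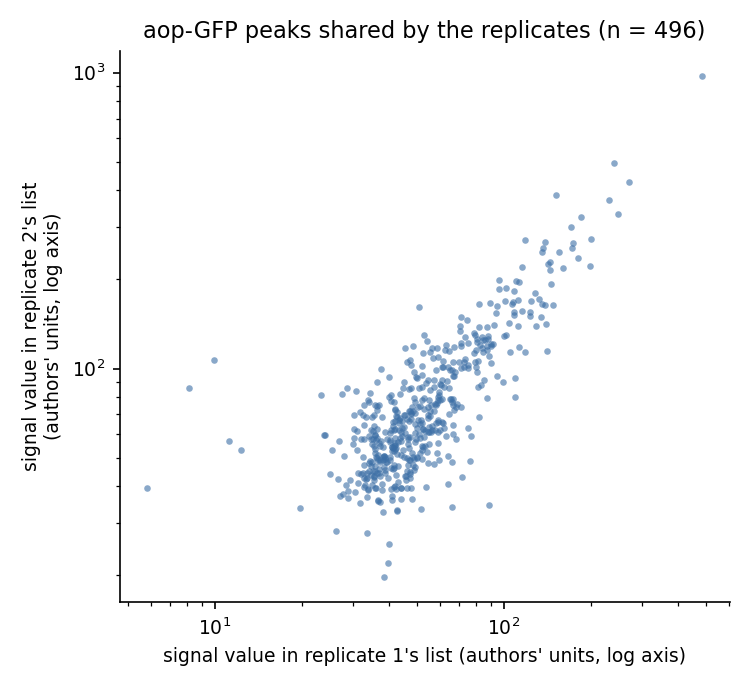
Signal value of each of the 496 peaks of replicate 1 that overlap a peak of replicate 2 (x axis, authors' units, log scale) against the value of the overlapping peak in replicate 2 (y axis, authors' units, log scale). Each point is 1 peak. The points rise together (Spearman rho 0.726), and the sty peak lies at the top right with 485 in replicate 1 and 976 in replicate 2.

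Peaks in one replicate's list alone were weaker than shared ones. In replicate 1, 132 such peaks had a median signal of 35.2 against 49.0 for shared peaks, and in replicate 2, 650 had 42.7 against 66.4 (permutation p = 1e-05 for the median rank in either list). The 5 strongest in replicate 1 alone were assigned to Btk (signal 72.2, an intron on 2L at 8292487 to 8292726), Sptz (59.6), COX7AL2 (56.3), Prps (50.4) and CG42808 (50.2). Btk encodes a Tec-family tyrosine kinase. At 4 of these places replicate 2 held a candidate outside its thresholded list, ranked 1425, 1062, 1644 and 711 by signal among its 113872 candidates for Btk, Sptz, Prps and CG42808. At COX7AL2 (intergenic, 2L 2201210 to 2201449), which lies within the stretch of raised signal around aop described further on, replicate 2 held none. The strongest in replicate 2 alone were those of CG3744 (92.7), HmgZ (90.0), lace (84.6), PKD (79.8) and LanA (78.5), which encodes a laminin subunit. All 5 were TSS-proximal. Replicate 1 held candidates outside its thresholded list at CG3744 (rank 424 of its 93043), lace (2276), PKD (635) and LanA (1432), and none at HmgZ. Of the 1692 thresholded peaks on the chromosome arms, 482 were in both replicates' own lists, 644 in one and 566 in neither. The conservative set held 1473 peaks, of which 1323 (89.8%, 88.2 to 91.3) overlapped the thresholded set. The 395 peaks that the thresholded set added had a median signal of 51.2, against 72.1 for the rest.

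The strongest aop-eGFP peak lay at sty. The 20 strongest also included peaks at aop and spi, which like sty are genes of receptor tyrosine kinase signalling. Most of the others lay at promoters of genes with varied known roles, and no test was run on these 20. The sty peak (3L 3418360 to 3418658, intron, 543 bp from a TSS) had a signal of 1468.5, about as much as the next pair together, msi with 724 (3R 25515431 to 25515665, intergenic) and CG14100 with 696 (3L 19590510 to 19590698). Best1, a bestrophin chloride channel gene, followed with 612 (3R 10170549 to 10170769), then Ugalt, a UDP-galactose transporter gene, with 583 (X 2703803 to 2704000). Among the 20 strongest, 3 peaks belonged to aop itself, with signals of 544 (2L 2161599 to 2161834, TSS-proximal), 406 (2L 2162301 to 2162672, intron) and 399 (2L 2171754 to 2171967, intron). The gene spi, which encodes the EGF receptor ligand Spitz, had 402 (2L 19575924 to 19576224, TSS-proximal). The rest were assigned to CG7601 (500.2), lobo (469), mRpL41 (469), Tcs5 (436), CenG1A (429), px (426), CG11050 (411), ph-p (410.1), scrib (385), eIF6 (381) and CG1888 (379.5). They include a mitochondrial ribosomal protein (mRpL41), a Polycomb group protein (ph-p), the cell polarity protein Scribble (scrib) and a translation initiation factor (eIF6). Of the 20 peaks, 15 were TSS-proximal and all 20 were in both replicates' own lists.

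An ETS site, the sequence class bound by aop and by its activating counterpart pnt, stood within 100 bp of the summit in 4 of these 20 peaks. The site in the sty peak was ACGGAAAT (3L 3418577 to 3418584, in the intron), and those at msi (3R 25515516 to 25515523, intergenic) and Best1 (3R 10170642 to 10170649, TSS-proximal) were both CCGGAAGT. The third aop peak held CCGGAAAT on the minus strand (2L 2171809 to 2171816, intron).

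Binding of aop-eGFP was concentrated at promoters and rare in coding sequence. Of the 1692 summits, 883 (52.2%, 49.8 to 54.6) were TSS-proximal, against 14.8% of the 143341 other candidates (odds ratio 6.29, 5.71 to 6.92, Fisher's exact p = 4.63e-278). Introns held 529 summits, among them the strongest peak of sty, and intergenic sequence held 218. Coding exons held only 27 summits (1.60%), against 19.5% of candidates (odds ratio 0.0670). Introns (31.3% against 37.9%, odds ratio 0.746), intergenic sequence (12.9% against 23.6%, 0.480), 3' UTRs (0.473% against 2.73%, 0.169) and 5' UTRs (0.473% against 0.966%, 0.487) were also below the candidates, and noncoding exons were above (1.12% against 0.60%, 1.88). The classes exclude each other and TSS-proximal came first, so its excess alone lowers the shares of the rest. Away from TSSs, 529 intron, 218 intergenic and 27 coding summits stood against 54279, 33768 and 27926 candidates. The lower shares of introns and intergenic sequence therefore do not show that peaks avoided them. All 7 classes passed Fisher's exact test after adjustment, the weakest being 5' UTRs (adjusted p = 0.0430) and noncoding exons (adjusted p = 0.0125). With the shorter list left by dropping a replicate, noncoding exons did not pass without replicate 1 (odds ratio 1.84, Fisher's exact adjusted p = 0.0544) or without replicate 2 (2.15, 0.0603), nor 5' UTRs without replicate 1 (0.632, 0.284), leaving 5 classes without replicate 1 and 6 without replicate 2. 5' UTRs did not pass with a TSS window of 250 bp (0.804, Fisher's exact adjusted p = 0.371) or 1 kb (0.322, 0.0501) or against random positions (0.589, 0.165) either, nor did noncoding exons with 1 kb (1.43, 0.285). The odds ratio of coding exons was 0.0220 without replicate 1 (6 summits) and 0.0273 without replicate 2 (4 summits), and without replicate 2 those of 3' UTRs and 5' UTRs, with 1 summit each, were 0.0594 and 0.168. In the 846 strongest peaks that of coding exons was 0.00979 (2 summits), and in the conservative set that of 5' UTRs was 0.213 (3 summits). The TSS-proximal share was 58.7% (53.3 to 64) among the 339 strongest peaks and 47.5% (42.1 to 53) among the 339 weakest.

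**Figure D2:**
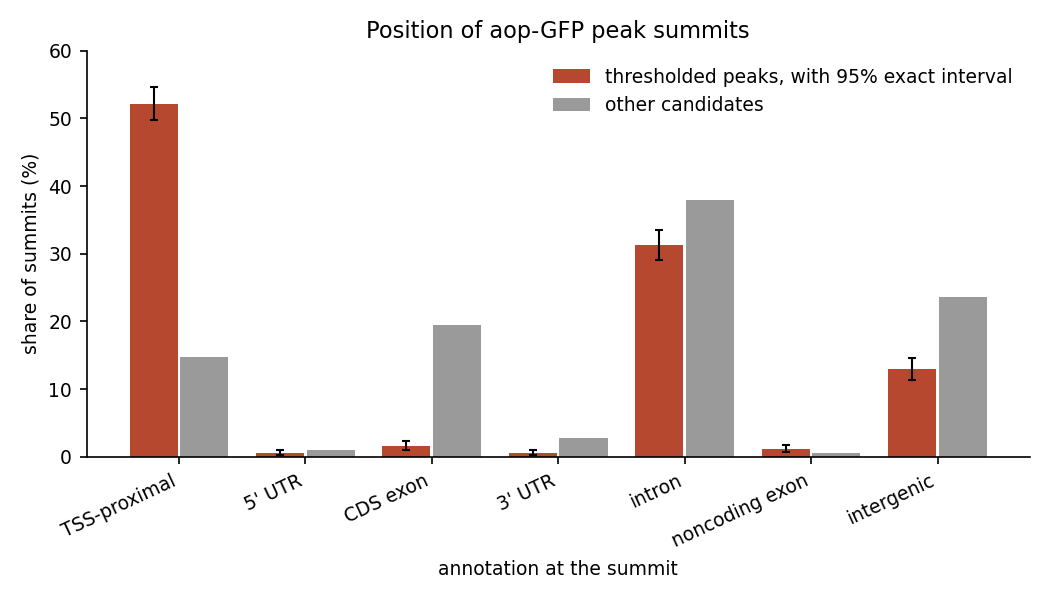
Share of summits (y axis, percent) in each annotation class (x axis) for the 1692 thresholded peaks (red bars, with exact 95% intervals) and the 143341 other candidates (grey bars). TSS-proximal summits make up 52.2% of the peaks and 14.8% of the candidates, and coding exons 1.60% and 19.5%.

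ETS sites were more frequent under aop-eGFP peaks than under matched candidates, but most peaks held none. The site MCGGAARY (M is A or C, R is A or G, Y is C or T) occurred within 100 bp of 126 of 1692 summits (7.45%, 6.24 to 8.80) and of 4.24% of matched candidates (odds ratio 1.82, 1.49 to 2.21, Fisher's exact p = 1.88e-08, adjusted p = 1.57e-07). The strict form ACCGGAAGT was found at 15 peaks (0.887% against 0.146%, odds ratio 6.10, 3.19 to 11.7, Fisher's exact p = 9.93e-07). Its odds ratio was 8.65 without replicate 1 and 10.1 without replicate 2, the latter from 7 peaks (3.53 to 28.9). The short core MGGAW, which occurs by chance in most windows, went the other way, with 66.9% of peaks and 71.0% of candidates (odds ratio 0.826, 0.742 to 0.919, Fisher's exact p = 0.000508). Sites were concentrated near the summit. Of 237 sites within 250 bp of a summit, 80 (33.8%, 27.8 to 40.2) lay within 50 bp, against 19.7% of those around matched candidates (odds ratio 2.08, 1.55 to 2.78, Fisher's exact p = 2.83e-06). The excess was found at promoters (63 of 883 peaks, odds ratio 1.75) and away from them (63 of 809, odds ratio 1.90). The ratio of these odds ratios, computed after seeing the data, was 0.921 (0.621 to 1.37), an interval that holds 1.

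For the ETS site MCGGAARY, no relation between peak strength and the number of sites was detected across all peaks. The number of sites and the signal had a Spearman rho of 0.0256 (permutation p = 0.293, over 1692 peaks). The 339 strongest peaks held the site in 10.03% of cases and the 339 weakest in 6.78%, with 6.80%, 4.73% and 8.88% in between. Within the 846 strongest peaks rho was 0.0918 (permutation p = 0.00739), and for the strict form over all peaks it was 0.0597 (permutation p = 0.0130). Among named targets, the pnt locus held 3 ETS sites under its peaks, ACGGAAAC (3R 23314528 to 23314535), ACGGAAGC (3R 23315417 to 23315424, minus strand) and CCGGAAAT (3R 23297332 to 23297339, minus strand). The aos locus held CCGGAAGT (3L 16473362 to 16473369), and the strongest peak of ed also held 1 site.

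**Figure D3:**
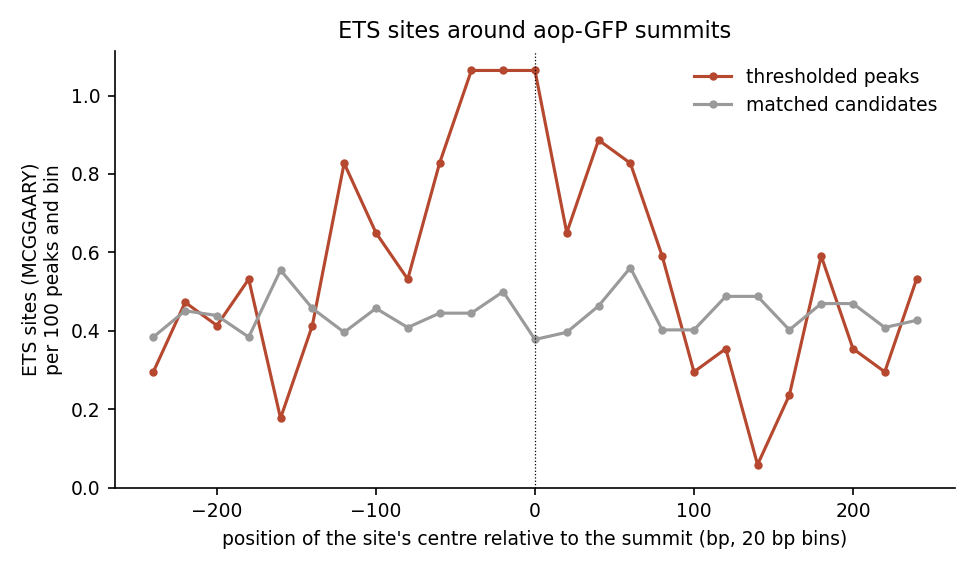
Number of ETS sites (MCGGAARY) per 100 peaks and 20 bp bin (y axis) by distance of the site's centre from the summit (x axis, bp) for the 1692 thresholded peaks (red) and the 16395 matched candidates (grey). Sites of the peaks gather at the summit, with 33.8% of those within 250 bp lying within 50 bp, against 19.7% for candidates.

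Among the sites of other factors, the sequence of the GAGA factor Trl had the largest excess by its p-value. GAGAGAG stood at 157 peaks (9.28% against 2.95%, odds ratio 3.36, 2.79 to 4.06, Fisher's exact adjusted p = 2.83e-29). The DREF/BEAF site TATCGATA (57 peaks, 3.37% against 1.37%, odds ratio 2.51, Fisher's exact adjusted p = 1.57e-07), the repeat CACACACACA (4.26% against 2.59%, 1.67, adjusted p = 0.000712) and the Mef2 site (8.51% against 6.29%, 1.38, adjusted p = 0.00233) were also more frequent. At TSS-proximal peaks the odds ratios were 2.70 for DREF/BEAF and 1.67 for Mef2 (Fisher's exact adjusted p = 1.57e-07 and 0.000337). Away from TSSs they were 1.21, from 4 peaks, and 1.08 (Fisher's exact adjusted p = 0.768 for both). Ratios of these odds ratios, 2.22 (0.751 to 6.59) and 1.55 (1.07 to 2.25), did not pass after adjustment. Below the candidates were the Snail E-box (6.38% against 8.36%, odds ratio 0.747, Fisher's exact adjusted p = 0.0122) and the TCF site (5.44% against 7.19%, 0.743, adjusted p = 0.0169). The other 13 sites did not pass Fisher's exact test, among them those of Zelda (1.36% against 1.12%, adjusted p = 0.462), AP-1 (adjusted p = 0.274), Su(H) (adjusted p = 0.411), Tinman (adjusted p = 0.376) and Twist (adjusted p = 0.376). The Hox/homeodomain site was among them (305 peaks, 18.03% against 20.2%, odds ratio 0.869, Fisher's exact adjusted p = 0.0755), but passed in 6 of 11 alternatives, each time below the background (odds ratios 0.770 to 0.886, adjusted p 0.000837 to 0.0335). Mad/Med passed in 5 of the 11, below in 4 and above within 250 bp (1.16), and 8 of the 13 sites passed in at least 1. DREF/BEAF rested on the combined list, with odds ratios of 1.43 (Fisher's exact adjusted p = 0.148) without replicate 1 and 0.931 without replicate 2. Mef2 did not pass without replicate 2 (1.30, Fisher's exact adjusted p = 0.257), nor did the Snail E-box (0.779, adjusted p = 0.495) or the TCF site (0.889, adjusted p = 0.881). The Snail E-box and the TCF site did not pass without replicate 1 either (0.796, Fisher's exact adjusted p = 0.148, and 0.830, adjusted p = 0.269). Nor did they in the conservative set (0.908, Fisher's exact adjusted p = 0.558, and 0.797, adjusted p = 0.124). In the 846 strongest peaks they did not pass either (0.784, Fisher's exact adjusted p = 0.250, and 0.798, adjusted p = 0.258).

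Genes reported as aop targets and genes of receptor tyrosine kinase signalling were bound far more often than matched genes. Of 13968 protein-coding genes, 1303 (9.33%) had at least 1 assigned peak. Of 19 reported target loci, 13 were bound, where random gene sets gave 3.61 ± 1.68 (SD over 10000 sets). Permutation p was 0.0002, the smallest these sets can give, and 0.00187 adjusted over the lists alone. That list was drawn from what the field has reported of aop, so it is not independent evidence. Its bound genes were sty (1468.5), aop (544), edl (161), aos (118), pnt (107), ed (106), dpp (85.4), pyd (63.3), mid (59.6), wg (58.8), Delta (56.8), twi (52.6) and rho (50.2), each with the signal of its strongest peak. Their products include the ETS activator pnt, the aop modulator edl, the secreted EGF receptor inhibitor Argos (aos) and the protease Rhomboid (rho), which releases Spitz. The other 6 genes of the list, eve, pros, sv, sna, ato and Egfr, had no assigned peak and are named here beyond the rule.

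Receptor tyrosine kinase and Ras/MAPK signalling had 20 of 48 genes bound against 7.32 ± 2.41 (permutation adjusted p = 0.00187, adjusted over the lists alone). The strongest were sty, aop, spi (402) and RasGAP1 (209.8, 3L 9855906 to 9856036, intergenic), a GTPase-activating protein of Ras. The call of this list held with either replicate's list alone (18 bound against 5.41 without replicate 1 and 17 against 3.24 without replicate 2, permutation adjusted p = 0.00280 in both). That of the reported targets held likewise, with the same adjusted p in either case, but not among the 846 strongest peaks (permutation adjusted p = 0.0579). The genes sty, aop, edl, aos, pnt, ed and rho are bound members of both lists, so these lists are not separate pieces of evidence. With aop left out, receptor tyrosine kinase signalling had 19 of 47 genes bound against 7.06 (permutation adjusted p = 0.00187).

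Several developmental pathways and the ribosomal protein genes were also bound more often than matched genes. Neither here nor for the lists above were genes matched on expression or open chromatin, so an effect of either was not tested. Dpp/BMP and Activin signalling had 11 of 27 genes bound against 3.77 (permutation adjusted p = 0.00560), led by shn (92.7, 2R 11184442 to 11184697, intron), ush (92.6), dpp (85.4, 2L 2433503 to 2433758, intron) and wit (83.1), a BMP receptor gene. Notch signalling had 9 of 30 against 3.52 (permutation adjusted p = 0.0325), with E(spl)m2-BFM (89.0), numb (78.5), neur (73.1) and Nedd4 (65.9). Dorsoventral patterning had 11 of 24 against 4.06 (permutation adjusted p = 0.0112), with ush, the FGF ligand gene ths (89.0), Mef2 (77.8) and tin (76.0). Genes of the central nervous system midline had 8 of 16 against 2.92 (permutation adjusted p = 0.0252), with spi, S (111), pnt and comm (75.8). Glial genes had 6 of 14 against 1.79 (permutation adjusted p = 0.0252), with moody (213), ttk (109), pnt and Nagk (53.3). Endoderm and gut genes had 9 of 22 against 3.55 (permutation adjusted p = 0.0305), with dpp, tin, cad (72.9) and upd1 (66.1). The ecdysone response had 8 of 19 against 3.21 (permutation adjusted p = 0.0367), with Hr3 (275), Hr4 (167), E23 (137) and Kr-h1 (117). Without replicate 2 the bound genes were 3 against 1.59 for Dpp/BMP, 1 against 1.54 for Notch, 2 against 1.84 for dorsoventral patterning and 1 against 1.53 for endoderm.

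Cytoplasmic ribosomal protein genes had 17 of 81 bound against 5.71 (permutation adjusted p = 0.00187), with RpS29 (245), RpS6 (124), RpL24 (116) and RpL7 (114.96), all TSS-proximal. None of 66 chemosensory receptor genes was bound (0 against 6.76, permutation adjusted p = 0.00560). Without replicate 1 the lists that passed were the reported targets, receptor tyrosine kinase signalling, Notch, dorsoventral patterning and the ecdysone response. Without replicate 2 only the reported targets and receptor tyrosine kinase signalling passed. With the conservative set those, Dpp/BMP, the ribosomal proteins and the ecdysone response were bound more often than matched genes, and Notch (permutation adjusted p = 1), dorsoventral patterning (0.0528), midline (0.463), glia (0.306) and endoderm (0.156) did not pass. Chemosensory receptors still had 0 bound genes with either replicate left out, against 4.72 without replicate 1 (permutation adjusted p = 0.0663) and 2.73 without replicate 2 (0.442), which did not pass. Among the 846 strongest peaks only receptor tyrosine kinase signalling passed (18 bound against 4.24, permutation adjusted p = 0.00560). Gene assignment decided some calls. When a TSS had to lie within 1 kb, the ecdysone response had 2 of 19 genes bound against 1.76 (permutation adjusted p = 1), and dorsoventral patterning (6 of 24 against 2.20, 0.0918), endoderm (6 of 22 against 1.91, 0.0566) and chemosensory receptors (0 of 66 against 4.51, 0.0566) did not pass either. With gene bodies and 2 kb upstream, the ecdysone response (7 of 19 against 3.03, permutation adjusted p = 0.104), endoderm (8 of 22 against 3.35, 0.0646) and chemosensory receptors (2 of 66 against 8.12, 0.0560) did not pass.

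Lists for the heart (8 of 23 bound against 3.91, permutation adjusted p = 0.137), mesoderm and muscle (10 of 44 against 7.27, 0.506), neurogenesis (10 of 37 against 6.06, 0.221), the tracheal system (6 of 26 against 4.69, 0.717) and the retina (7 of 31 against 5.58, 0.717) did not pass. Their strongest bound genes were pnt (107), Doc2 (77.9), tin and zfh1 (71.1) for the heart. For mesoderm they were org-1 (167), kirre (93.7), Mef2 and tin. Neurogenesis had elav (151), brat (133), grh (80.9) and numb. The tracheal list had sty, pnt, dpp and grh, and the retinal list had dpp, hth (83.9), salm (68.8) and eyg (58.5). These lists share members, as the repeated names of pnt, dpp and tin show, so they are not separate pieces of evidence.

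**Figure D4:**
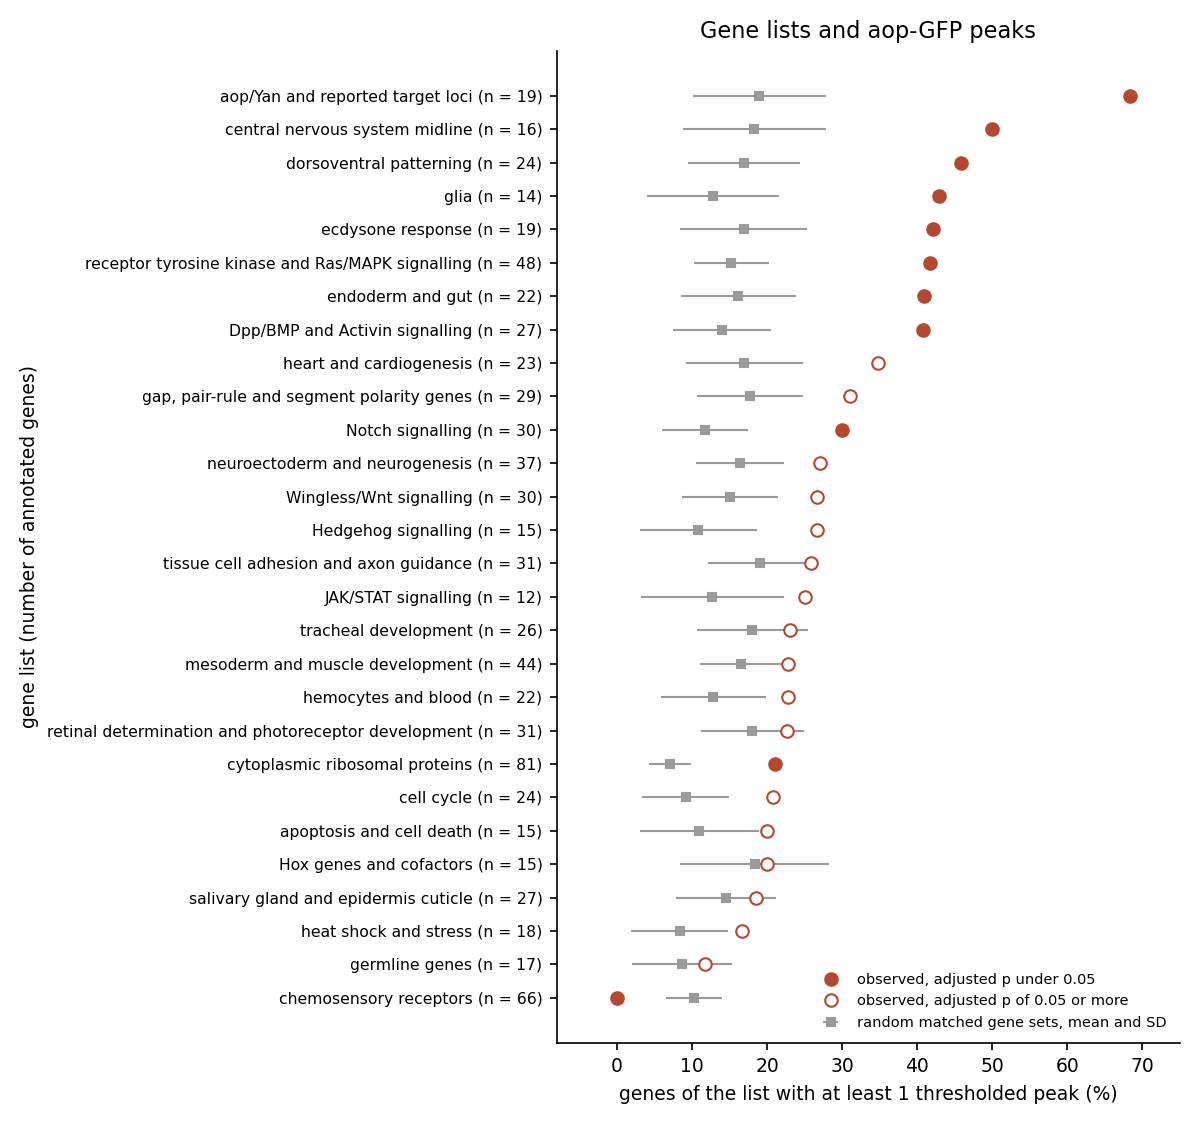
Percent of the genes of each list with at least 1 thresholded peak (x axis) for the 28 lists (y axis, with the number of annotated genes). Red circles are observed values, filled where the adjusted p is under 0.05, and grey squares with bars are the mean and SD of 10000 matched random gene sets. Reported aop targets stand at 68.4%, receptor tyrosine kinase and Ras/MAPK signalling at 41.7% and chemosensory receptors at 0%.

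The aop gene collected more peaks than any other gene. It had 20 peaks over 21.2 kb (2L, summits 2161713 to 2182864), of which 10 were in replicate 1's own list, 16 in replicate 2's and 2 held an ETS site. The weaker candidates between these peaks were raised too. The 22 that did not overlap a thresholded peak had a median signal of 25.3, against a median of 15.8 over windows of the same length elsewhere. The longest run of adjacent 5 kb bins with a median candidate signal above the upper quartile of all bins (19.0) spanned 60 kb around the gene (2L 2145001 to 2205000), a scan chosen after seeing the data. Others with many peaks were sty with 7, sbb and pnt with 6, Tlk, CHES-1-like and brat with 5, and HmgZ and Ptpmeg2 with 4. HmgZ and Ptpmeg2 were taken by their highest signal from several genes with 4. The 6 peaks of pnt spanned 36.9 kb (3R, summits 23297353 to 23334286) and 3 of them held an ETS site.

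**Figure D5:**
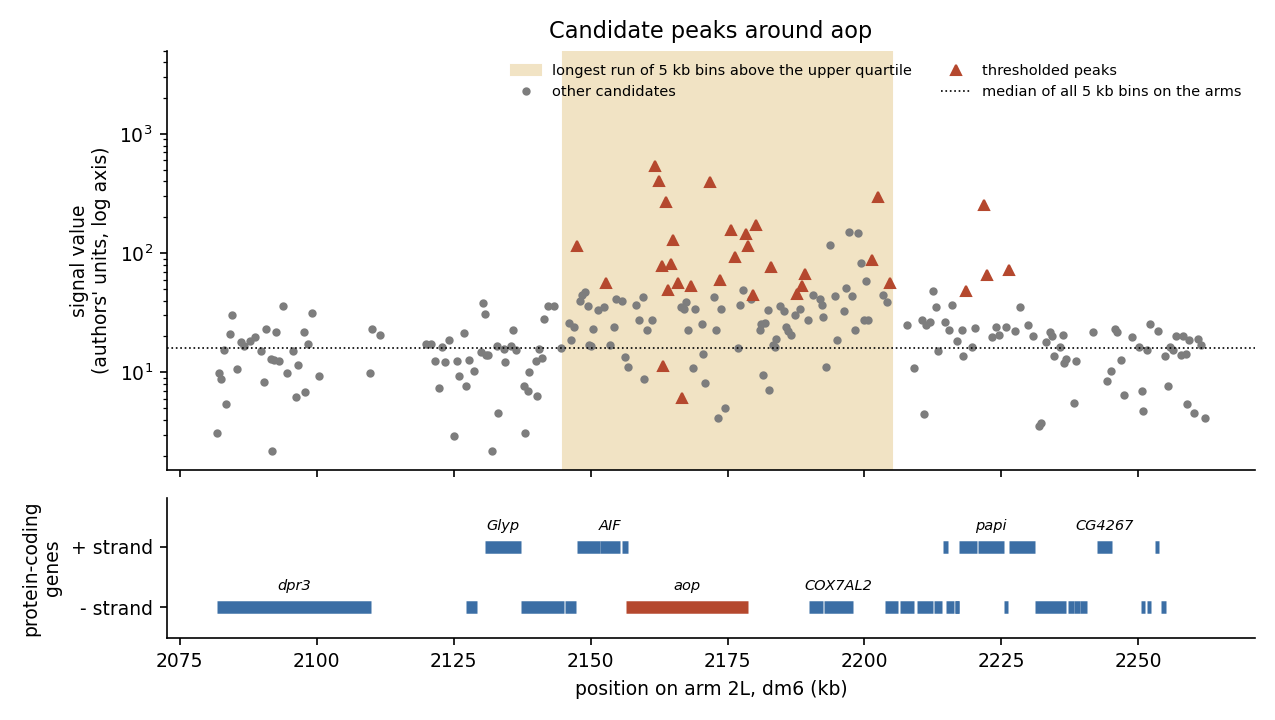
Signal value of every candidate peak (y axis, authors' units, log scale) by position on arm 2L (x axis, kb, dm6), from both replicates together, with protein-coding genes by strand in the lower panel. Red triangles are thresholded peaks, grey points are other candidates, the dotted line is the median of all 5 kb bins (16.0) and the shaded stretch is the 60 kb run of raised bins that contains aop.

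Multiple peaks within a locus were more frequent than chance. In all, 85 genes had at least 3 peaks, against 40.4 on average and 60 at most in random draws of candidates (permutation p = 0.000999), while 166 genes had 2 and 1052 had 1. With replicate 1's own list alone the count was 9 against 4.04 (permutation p = 0.0140), and with replicate 2's it was 32 against 14.7 (permutation p = 0.000999). Of the 1692 peaks, 624 (36.9%, 34.6 to 39.2) had another within 5 kb, against 13.1% on average and 16.8% at most (permutation p = 0.000999). Draws matched on TSS proximity gave 15.2%. The draws for peaks per gene were not matched in this way. Among all 1725 thresholded peaks, 29 adjacent pairs overlapped, and the peaks of such a pair were counted separately.

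Only arm 3R differed from the candidates in its share of peaks. It held 377 of 1692 peaks (22.3% against 25.5%, odds ratio 0.839, 0.748 to 0.941, Fisher's exact adjusted p = 0.0185). Arms 2L (342 peaks, odds ratio 1.15) and 3L (379, 1.15) both had an adjusted p of 0.0513. Arm 4 held 1 peak, that of PlexA, named after its values were seen, and Y held 0. Without replicate 2 no arm passed (3R at 0.825, Fisher's exact adjusted p = 0.121). Against arm length instead of candidates 3R did not pass (ratio of its share of peaks to its share of length 0.955, exact binomial adjusted p = 0.460), while 2L was above (1.18, adjusted p = 0.00204) and arms 4 and Y were below. The peaks of 2L include the 20 of aop, in the stretch of raised signal, and no test of arms left these out.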

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

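All tests in this part were chosen after the lists had been seen. The score of the thresholded set was also reached by 101 candidates of the ranked list that the set left out, 23 of them on unplaced sequence and 78 on the arms. Their median signal was 65.2, close to the 64.9 of the set itself. Of the 78, 10 lay in annotated transposons (12.8%, 6.32 to 22.3), against 5 of 1692 thresholded peaks (0.296%; odds ratio 49.6, 16.5 to 149, Fisher's exact p = 3.9e-11), and 30 were TSS-proximal. Many of the 78 lay close together, as at tara, cbt and CG14621, so the intervals and the p-value treat neighbours as independent. Those assigned to COX7AL2 (2L 2193574 to 2200426) lay within the stretch of raised signal around aop. The strongest left-out candidate on the arms, named after its value was seen, was assigned to Lk6 (signal 459, 3R 11760959 to 11761137), 964 bp from a TSS. A further 33 thresholded peaks lay on unplaced or unlocalised sequence, and no comparison of genes or motifs used them. There was 1 group of 2 samples, so samples apart from their group and differences between groups were not tested.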

How the results depend on the processing

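Leaving out peaks with a signal under 20, the peaks of aop, or aop from the gene lists were tests chosen after seeing the data, and the other alternatives were planned. Of 106 alternatives to the values that answer a comparison, 87 kept direction and side of the threshold, 2 newly passed, 2 reversed and 15 moved. Of 549 for single classes, motifs, lists and arms, 414 were unchanged in this sense, 61 no longer passed, 29 newly passed and 45 reversed. Ranges were 4.94 to 8.07 for the promoter odds ratio, 1.27 to 2.22 for the ETS site except in its strict form (6.10) and its short core (0.826, reversed), and 0.669 to 0.738 for the correlation of replicates. The clustering ratio stayed between 1.99 and 4.26. Against the other replicate's whole ranked list, 97.9% of the peaks of replicate 1 found a partner, which a list of candidates so long makes easier. The relation of ETS sites to strength passed in the 846 strongest peaks (rho 0.0918) and for the strict form (0.0597). The count of other motifs above background, 4, was 2 without replicate 2, 3 without replicate 1 and 7 within 250 bp of the summit. The count of bound lists, 10, was 5 with the conservative set, 1 in the 846 strongest peaks, 5 without replicate 1, 2 without replicate 2 and 18 by Fisher's test without matching, where large loci are no longer compared with large loci. Genes with at least 3 peaks, 85, were 20 in the 846 strongest peaks, 32 without replicate 1, 9 without replicate 2 and 13 when a TSS had to lie within 1 kb, settings with fewer peaks by construction. The count of arms that passed, 1, was 2 with the conservative set (3R and 2L), 3 against arm length (2L, 4 and Y, not 3R), 0 without replicate 2 and 1 without replicate 1. Single results that reversed and passed in either setting were DREF/BEAF without replicate 2 (odds ratio 0.931, and 1.43 without replicate 1), Mad/Med within 250 bp (1.16), the Notch (ratio of bound to expected genes 0.651, and 3.15 without replicate 1) and endoderm (0.655 and 2.31) lists without replicate 2, and arm 4 against arm length (0.0603). The reversals that follow passed in neither setting. Without replicate 2 and without replicate 1, odds ratios were 0.712 and 1.15 for Zelda, 0.881 and 1.503 for AP-1, 0.704 and 1.39 for Grainyhead, 1.08 and 0.960 for Mad/Med, 0.885 and 1.30 for Motif 1, and 0.869 and 1.47 for T-box. In the same order, list ratios were 0.448 and 1.62 for segmentation, 0.804 and 1.45 for Hox genes, 0.569 and 2.08 for the heart, 0.792 and 1.43 for the retina and 0 and 0.956 for germline genes. Arms gave 0.838 and 1.09 (2R), 0.967 and 1.08 (3L), 2.07 and 0.696 (4) and 1.28 and 0.972 (X). The conservative set reversed T-box (0.956), Hox genes (0.797), neurogenesis (0.918), salivary gland (0.863), germline (0.771) and arm X (1.06). The 846 strongest peaks reversed Tinman (1.003), Grainyhead (0.821), Motif 1 (0.881), T-box (0.713), salivary gland (0.882), the retina (0.922) and arm X (1.09). Windows of 50 bp reversed Twist (0.964) and T-box (0.553), and 250 bp T-box (0.954). Unmatched candidates reversed Twist (0.960) and Hox/homeodomain (1.02), and flanks Zelda (0.904), GATA (0.983), Grainyhead (0.997) and T-box (0.585). Gene bodies reversed heat shock genes (0.968), arm length reversed 2R (1.01), and the short ETS core turned the relation to strength to a rho of -0.0308. Apart from the settings with fewer peaks or no matching, the cause was not tested. No paired analysis was possible because there is 1 group. Read depth is unknown, so it cannot be said which absent peaks depth would have allowed.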

Other observations

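The test of spreading signal, its flanking values and the run of 5 kb bins were chosen only after the raised signal around aop had been seen. Bound genes also occurred in lists that did not pass, and they are named here after their values were seen. Wingless/Wnt signalling had 8 of 30 genes bound against 4.52 (permutation adjusted p = 0.221), with sgg, the kinase GSK3, at a signal of 122 and the glypican dlp at 91.3. Hedgehog signalling had 4 of 15 against 1.63 (0.221), with rdx at 83.9 and the receptor ptc at 46.7. JAK/STAT signalling had 3 of 12 against 1.52 (0.506), with chinmo at 180.3 and the feedback inhibitor Socs36E at 72.7. Segmentation genes had 9 of 29 against 5.14 (0.221), with slp2 at 107, and Hox genes and cofactors had 3 of 15 against 2.75 (permutation adjusted p = 1), with hth at 83.9 and Antp at 78.0.

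The cell cycle list had 5 of 24 genes bound against 2.19 (permutation adjusted p = 0.221), with CycB at 206 and the phosphatase gene stg at 50.05. Apoptosis had 3 of 15 against 1.64 (0.536), with Diap1 at 84.1 and rpr at 48.8. Heat shock genes had 3 of 18 against 1.5 (0.506), with Hsp27 at 133. Blood cells had 5 of 22 against 2.82 (0.416), with ush at 92.6 and the scavenger receptor crq at 88.3. Salivary gland and cuticle genes had 5 of 27 against 3.92 (0.763), adhesion and axon guidance 8 of 31 against 5.91 (0.536), and germline genes 2 of 17 against 1.48 (0.923).

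Many peaks at aop may partly reflect the tagged construct. Extra copies of a tagged fragment would raise every position of the fragment, and the 22 candidates at the locus that overlapped no thresholded peak had a median signal at percentile 99.9 of 23315 windows (25.3, against 21.5 at the upper end of the central 95% of windows), as that explanation needs. Signal spreading from neighbouring peaks cannot be told apart from this. Although the same median stood at percentile 99.3 of 10000 draws matched on distance to the nearest peak, each of these candidates had at least 10 peaks that pass the score within 10 kb, and none of those drawn from had more than 7. The flanks of 20 kb, which also hold peaks, had medians of 27.3 (27 candidates, left) and 27.7 (23, right), and the 12 on the left more than 2 kb from a peak had 25.4, so the raised signal went beyond the span, while the reach of spreading and the ends of a tagged fragment are not known. Whether ETS sites at the locus contribute cannot be told apart from chance with 20 peaks, of which 2 held a site (odds ratio 1.74, 0.361 to 8.39, Fisher's exact p = 0.370), and no other biological explanation was tested.

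The concentration of peaks at promoters may have been open chromatin captured without the factor's own site, or the site may have been enriched at promoters alone. The ETS odds ratio away from promoters, 1.90 (1.43 to 2.51, Fisher's exact p = 2.84e-05), argues against enrichment at promoters alone. At promoters it was 1.75 (1.32 to 2.31, Fisher's exact p = 0.000214), where capture of open chromatin without the site predicted an interval that holds 1. The candidates were matched on GC content and TSS proximity but not on open chromatin, so this excess cannot decide whether open promoters were captured. The ETS site was present at only 7.13% of promoter peaks and 7.79% of the others, so how the remaining peaks arise stays open. Other promoter factors were not tested as a cause, and control libraries were not analysed here.

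Replicate 1 had fewer peaks, and lower sensitivity is a candidate explanation. Of the 650 peaks in replicate 2's list alone, 385 (59.2%, 55.3 to 63.0) lay among the top 5% of candidates in replicate 1, against 4.65% by chance and 7.85% at most, and 581 (89.4%) matched some candidate. Places bound in one replicate alone cannot be told apart from this, since the remaining 40.8% (37.0 to 44.7) is the complement of the same count and no separate test. A difference in depth remains open because read depth is unknown. The embryos were collected over 24 h, and a difference in their ages between replicates was not tested.

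The run of raised bins at aop was 12 bins long, and the second longest run had 9 bins (3R 8710001 to 8755000).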
